A study of Mus musculus with 8 samples.

How the data were processed

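RNA sequencing was performed on total RNA from scraped back-skin epidermis of female wild-type and REDD1 knockout mice, giving 8 libraries in 6 groups of genotype and treatment. Per the submitters' processing notes, reads were trimmed with Trim Galore, aligned with STAR to mm10 and counted with HTSeq. Versions, the annotation release, the strand setting and filters are not given in the sources used here. Each deposited file held raw read counts per Ensembl gene for 1 library, which the authors had not normalised. The files listed 54232 gene identifiers and no lines for reads outside genes, so those reads were not analysed here. Because the strand setting is unknown, reads of overlapping and antisense genes cannot be told apart, and reads of near-identical copies can have been split or dropped. The 13 protein genes of the mitochondrial genome were listed at 0 in all 8 libraries, so mitochondrial RNA was not used as a sign of quality.

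Gene symbols and coordinates were taken from GENCODE M21 annotation of the mouse assembly that mm10 names. Of the identifiers, 54165 matched and 67 did not, and 211 had a symbol shared with at least 1 other identifier. Groups and replicate numbers were taken from the labels. Library totals ranged from 16874233 to 22560098 counts, and a floor of 3 counts, covering counting error only, ranged from 0.133 to 0.178 CPM. CPM values were computed from the deposited counts and normalised by TMM, with factors from 0.859 to 1.102. The vehicle replicates, numbered as separate samples in the labels, differed by more than sampling noise, with a chi-square per degree of freedom of 31.19 in wild type and 13.95 in knockout. Neither pair was therefore taken as 1 library deposited under both numbers, and the test does not show whether they came from separate animals.

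Counts were tested with edgeR 4.0.16 in R 4.3.3, using quasi-likelihood F tests, TMM normalisation and filterByExpr by treatment with a minimum count of 10, which left 19251 genes. P-values were adjusted by the Benjamini-Hochberg method at a threshold of 0.05. TPA against vehicle, FA+TPA against TPA, FA+TPA against vehicle and knockout against wild type over all treatments were fitted additively for genotype and treatment on all 8 libraries, with 4 residual degrees of freedom. A genotype-specific response enters the spread of that fit. Knockout against wild type in vehicle skin and the interactions of genotype with TPA and with FA were fitted with 1 mean per group, with 2 residual degrees of freedom from the vehicle pairs. The single treated libraries were then assumed to vary like the vehicle pairs. Standard errors were the absolute log2 fold change divided by the square root of F. The edgeR fits and camera were tested on simulated counts for the real genes, drawn independently, with 200 changed genes. No genotype-specific response was simulated for the additive fits. The fitted tests made between 2 and 13 false calls per comparison, and 8 of 69 calls were false for the FA interaction.

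The designs, the processing alternatives and 32 gene lists were fixed before the data were examined. Lists covered cytokines and chemokines, antimicrobial genes, stress keratins, epidermal differentiation, basal genes, cell cycle, NF-kB feedback, AP-1, proteases and EGFR ligands, eicosanoids, glucocorticoid targets, glycolysis, cholesterol synthesis, ATF4, NRF2, hypoxia, interferon response, oxidative phosphorylation, mitochondrially encoded genes, and markers of neutrophils, macrophages, Langerhans cells, T cells, fibroblasts, skeletal muscle, adipocytes, endothelium, hair shaft, follicle stem cells, sebaceous glands, melanocytes and erythroid cells. The 30 lists with at least 3 measured members were tested with camera in limma 3.58.1 with a preset correlation of 0.01, adjusted over lists, and again with an estimated correlation. Members were counted past the threshold over all genes tested, and over the list alone. Where a count over the list alone is not given, it was the same as the count over all genes.

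Genes were named by a rule. It took Ddit4, then the 6 largest rises and 6 largest falls per comparison among genes past the threshold with a mean log2 CPM of at least 2, in the same direction in both genotypes for treatments. Names made only of an identifier, starting with Gm and digits or ending in Rik were left out. From each list it took up to 2 members past the threshold with the smallest p, or the member with the smallest p. Ddit4l, Sesn1, Sesn2, Sesn3, Tsc1, Tsc2 and Txnip were always taken. Some genes that the rule takes are not reported here. Genes named outside a comparison's own rule were taken from its naming in another comparison.

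Alternatives were RLE normalisation, library size only, no low-count filter, a minimum count of 50, 1 mean per group, limma-voom, DESeq2 1.42.0, each library left out in turn, vehicle libraries alone with and without a replicate block, and removal of genes within 10 Mb of Ddit4. Removal of the transcripts Gm26917 and Gm23935 was added after the data were examined. Tables and figures were made with Python 3.11.15, pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9.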

Results

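Gene expression was measured by RNA sequencing in scraped back-skin epidermis of female wild-type and REDD1 knockout mice on a mixed C57Bl and 129 background. REDD1, encoded by Ddit4, is a stress-induced inhibitor of mTORC1 signalling that glucocorticoids also induce. Shaved skin received acetone vehicle (200 ul), the phorbol ester TPA (4 ug), a tumour promoter and irritant, or fluocinolone acetonide (FA, 2 ug), a topical glucocorticoid, 1 h before TPA, and was taken 24 h after TPA. The 8 libraries comprised 2 wild-type vehicle, 2 knockout vehicle, and 1 library of each genotype for TPA and for FA+TPA. Total gene counts ranged from 16874233 to 22560098 per library, so 3 counts, the limit that a count of 0 allows, corresponded to between 0.133 and 0.178 CPM, counts scaled to library size. The treated groups had no replicates within a genotype. Treatment effects were therefore fitted over both genotypes, and p-values measured the spread between these samples, which may be technical because the labels do not say more about the replicates. The noncoding transcript Gm26917 took between 8.34% and 13.83% of the counts in vehicle libraries and between 16.77% and 24.21% in treated libraries. Changes are given as log2 fold change ± standard error (SE), and levels are normalised CPM.

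Ddit4 (ENSMUSG00000020108; mm10 chromosome 10, 59949669 to 59951834, minus strand, protein coding) was lower in each knockout library than in any wild-type library. In vehicle skin its level was 122.0 ± 7.92 CPM (SD, n = 2) in wild type and 18.7 ± 0.134 CPM (SD, n = 2) in knockout. Under TPA it was 64.2 CPM in wild type and 4.44 CPM in knockout, and under FA+TPA 90.3 and 7.25 CPM. Over all treatments the knockout difference was -3.16 ± 0.18 (edgeR adjusted p = 1.2e-05). With TPA, Ddit4 changed by -1.38 ± 0.22 over both genotypes (edgeR adjusted p = 0.000496). FA given before TPA was accompanied by a difference of 0.55 ± 0.25 from TPA alone. With 1 treated library left out it ranged from 0.13 (without wild-type FA+TPA) to 1.14 (without wild-type TPA). The difference over all libraries did not pass the test (edgeR adjusted p = 0.205). Over the alternatives that edgeR adjusted p ranged from 0.0191 to 0.917, and it passed without the low-count filter (0.0191) and with 1 mean per group (0.0241). FA+TPA differed from vehicle by -0.82 ± 0.22 (edgeR adjusted p = 0.0143), a call that ended without the knockout FA+TPA library (-0.60). In proportion the fall was smaller in wild type, from 122.0 to 90.3 CPM, than in knockout, from 18.7 to 7.25 CPM.

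**Figure D1:**
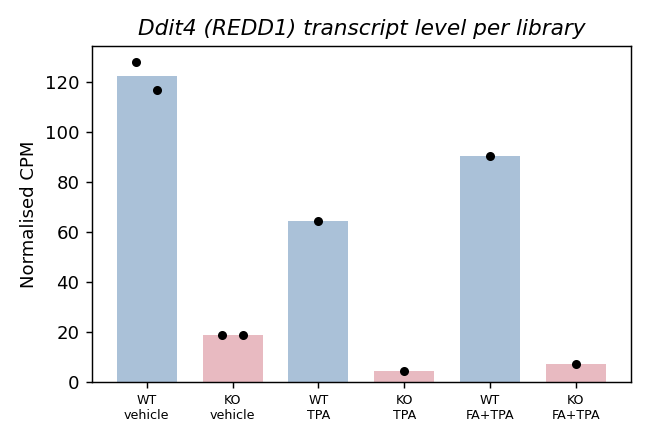
Normalised CPM of Ddit4 in each library, by genotype (WT, wild type, blue; KO, REDD1 knockout, pink) and treatment. Points are libraries and bars are group means. The knockout libraries sit between 4.44 and 18.8 CPM, and the wild-type libraries between 64.2 and 128.0 CPM.

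The response of the epidermis to TPA was assessed against vehicle over both genotypes. TPA raised the keratins and cornified envelope proteins of activated epidermis, proteases, inflammatory cytokines, antimicrobial proteins, cell cycle genes and glycolytic enzymes, while Langerhans cell and T cell transcripts fell. Krt6b (ENSMUSG00000023041; chromosome 15, 101676023 to 101680287), a keratin induced in activated keratinocytes, went from between 3.11 and 7.63 CPM in the 4 vehicle libraries to 3610 CPM in wild type and 2460 CPM in knockout (9.0 ± 0.28). Its paralogue Krt6a rose by 7.37 ± 0.23 and the kallikrein protease Klk6 by 7.55 ± 0.26. The late cornified envelope gene Lce3d was at most 0.155 CPM in each vehicle library and reached 30.8 CPM in wild type and 15.6 CPM in knockout. Sprr2f was at most 0.207 CPM in each vehicle library and reached 43.1 CPM in wild type and 22.7 CPM in knockout. Cd300lf, an inhibitory receptor of myeloid cells, was at most 0.0938 CPM in each vehicle library and reached 11.2 and 21.4 CPM. Among transcripts that fell, the differentiation-associated metallothionein Mt4 (ENSMUSG00000031757; chromosome 8, 94137197 to 94139031) changed by -5.55 ± 0.32, the natriuretic peptide clearance receptor Npr3 by -4.98 ± 0.28, the glutamine transporter Slc38a3 by -4.57 ± 0.30, Wfdc21 by -4.41 ± 0.18 and the carbonic anhydrase Car6 by -4.04 ± 0.39. Each was lower in both genotypes. Upk3b went from between 6.36 and 7.50 CPM in vehicle to 0.0616 CPM in wild type and 0.224 CPM in knockout.

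The stress keratin and small proline-rich protein list rose as a whole, with 17 of 17 measured members up and a median of 5.95 (camera adjusted p = 4.37e-14, adjusted p = 0.221 with an estimated correlation). Of 12 antimicrobial and alarmin genes, 11 rose (12 adjusted over the list alone), with a median of 5.20 (camera adjusted p = 1.53e-07, adjusted p = 0.3 with an estimated correlation). Examples were the protease inhibitor Slpi (6.39 ± 0.43) and the beta-defensin Defb14 (2.95 ± 0.18). Cytokines and chemokines had 16 of 21 members up (16 up and 1 down adjusted over the list alone) and a median of 2.26 (camera adjusted p = 1.16e-07, adjusted p = 0.14 with an estimated correlation), among them Tslp (3.68 ± 0.23) and the interleukin-36 gene Il1f9 (1.88 ± 0.11). Proteases and EGFR ligands had 15 of 17 up (16 adjusted over the list alone) and a median of 2.87 (camera adjusted p = 1.61e-09, adjusted p = 0.108 with an estimated correlation). The matrix protein gene Tnc rose by 5.03 ± 0.10 and the stromelysin gene Mmp3 by 6.38 ± 0.23. The collagenase gene Mmp13 (ENSMUSG00000050578; chromosome 9, 7272514 to 7283331) went from at most 0.227 CPM in vehicle to 28.7 CPM in wild type and 29.6 CPM in knockout. NF-kB feedback genes had 9 of 18 up and 1 down (camera adjusted p = 0.00399, adjusted p = 0.378 with an estimated correlation), led by Bcl3 (3.48 ± 0.20). AP-1 and early response genes had 10 of 14 up and 1 down (camera adjusted p = 0.00181, adjusted p = 0.221 with an estimated correlation), with Ier3 at 2.02 ± 0.16.

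Proliferation and metabolism moved in the same samples. Of 36 cell cycle genes, 31 rose (32 adjusted over the list alone), with a median of 1.81 (camera adjusted p = 3.91e-15, adjusted p = 0.221 with an estimated correlation), including the mitotic regulators Cdc20 (2.41 ± 0.12) and Plk1 (2.75 ± 0.16). All 15 glycolysis genes rose, with a median of 1.52 (camera adjusted p = 1.39e-11, adjusted p = 0.221 with an estimated correlation), such as the hexokinase Hk2 (2.69 ± 0.13) and the pyruvate kinase Pkm (1.91 ± 0.08). Nuclear genes of oxidative phosphorylation had 25 of 26 up by a smaller median of 0.49 (camera adjusted p = 5.73e-08, adjusted p = 0.3 with an estimated correlation), with Atp5b at 0.95 ± 0.10. ATF4 targets had 15 of 17 up (camera adjusted p = 2.15e-07, adjusted p = 0.221 with an estimated correlation), including the amino acid transporter Slc7a5 (1.40 ± 0.09) and the tRNA synthetase Aars (1.34 ± 0.08). Hypoxia-associated genes had 11 of 14 up and 2 down (camera adjusted p = 0.000316, adjusted p = 0.221 with an estimated correlation), with Bhlhe40 at 2.00 ± 0.11 and Egln3 at 1.94 ± 0.09. Cholesterol synthesis had 13 of 23 up and 1 down (camera adjusted p = 0.00306, adjusted p = 0.617 with an estimated correlation), with Sqle at 0.98 ± 0.14. That call was lost without the wild-type TPA library (camera adjusted p = 0.145).

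Epidermal differentiation genes went both ways, with 21 of 38 up and 8 down (9 down adjusted over the list alone) and a median of 0.57 (camera adjusted p = 0.00235, adjusted p = 0.516 with an estimated correlation). The desquamation protease Klk7 rose by 1.99 ± 0.13, whereas Lce1m, of the late cornified envelope family, changed by -2.36 ± 0.10. Basal and hemidesmosome genes were not called (camera adjusted p = 0.88), with 5 of 14 up and 6 down. The basal keratin Krt14 rose by 1.58 ± 0.09 and the hemidesmosome linker Dst changed by -2.04 ± 0.13. Their median was 0.05, while their mean of -0.17 and the test direction were negative. Known glucocorticoid targets had 4 of 20 up and 12 down, with a median of -0.73 (camera adjusted p = 0.0228, adjusted p = 0.378 with an estimated correlation). The transcription factor Klf9 changed by -2.12 ± 0.19, while the metallothionein Mt2 rose by 1.72 ± 0.11. With scaling by library size only, that call was lost (camera adjusted p = 0.0528).

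Markers of other cell types also moved with TPA. Neutrophil genes had 5 of 6 up and a median of 4.82 (camera adjusted p = 0.00286, adjusted p = 0.246 with an estimated correlation), including the granulocyte receptors Csf3r (6.51 ± 0.37) and Cxcr2 (4.41 ± 0.22). Macrophage and monocyte genes had 8 of 11 up and 1 down (camera adjusted p = 0.00121, adjusted p = 0.378 with an estimated correlation), with Mrc1 at 5.24 ± 0.41 and C1qc at 3.12 ± 0.26. Langerhans cell and MHC class II genes had 7 of 8 down and a median of -0.89 (camera adjusted p = 0.000273, adjusted p = 0.246 with an estimated correlation), including langerin, Cd207 (-1.45 ± 0.13). T cell genes had 8 of 13 down and 1 up (camera adjusted p = 0.00641, adjusted p = 0.347 with an estimated correlation), with the gamma-delta receptor constant gene Trdc at -2.66 ± 0.23 and Cd3e at -1.46 ± 0.15. Fibroblast (camera adjusted p = 0.786), skeletal muscle (0.247), adipocyte (0.746) and melanocyte (0.548) lists were not called. Of the genes related to REDD1 and its pathway, the redox regulator Txnip changed by -3.11 ± 0.35, Sesn1 by -1.42 ± 0.12, Sesn3 by -0.50 ± 0.11 and Tsc1 by -0.30 ± 0.09, and Sesn2 rose by 0.41 ± 0.11. Tsc2 (-0.07 ± 0.08) and Ddit4l (-0.25 ± 0.51) did not pass.

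In total 8852 of 19251 tested genes passed the test against vehicle, of which 4472 rose and 4380 fell, 1711 and 1840 of them by more than 2-fold. The edgeR adjusted p of the genes named as changed with TPA was at most 0.015. With scaling by library size only, all genes shifted by a median of -0.253 and the split became 2846 up and 6432 down. The call of Sesn2 ended without the wild-type TPA library (edgeR adjusted p = 0.102) and with library size only (0.194), that of Sesn3 without the knockout TPA library (0.0606), and that of Tsc1 without either (up to 0.273). No list call held with an estimated correlation between genes in this or any other comparison. In simulated data over 19251 genes with 200 changed, far fewer than were called here, 64% of 2-fold and 91% of 4-fold changes were recovered.

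**Figure D2:**
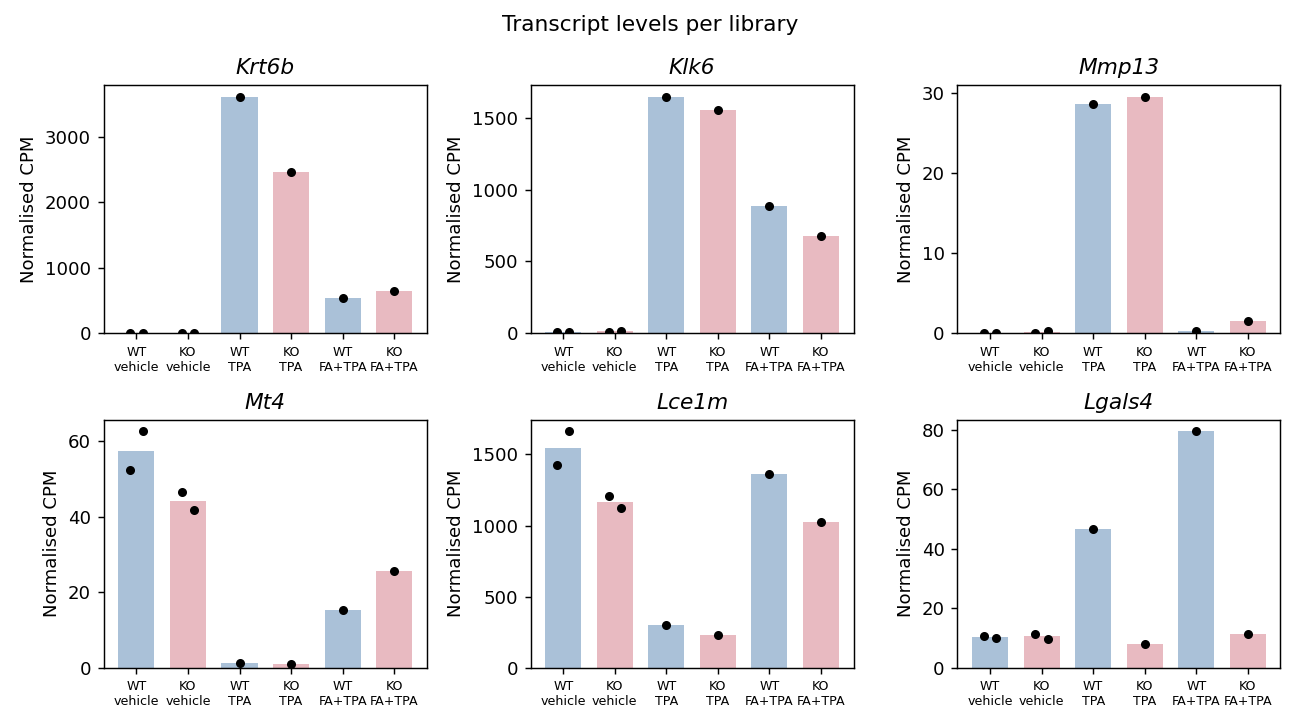
Normalised CPM of 6 genes in each library (blue, wild type; pink, REDD1 knockout); points are libraries, bars are group means and each axis starts at 0. Krt6b, Klk6 and Mmp13 were high under TPA, Mt4 and Lce1m were low, and Lgals4 reached 46.6 CPM under TPA in wild type against 7.86 CPM in knockout.

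The effect of the glucocorticoid on the TPA response was assessed by comparing FA+TPA with TPA alone over both genotypes. Known glucocorticoid targets and epidermal differentiation genes rose with FA, and stress keratins, proteases, cytokines and NF-kB feedback genes fell. The flavin monooxygenase Fmo2 (ENSMUSG00000040170; chromosome 1, 162874317 to 162898726) rose by 4.82 ± 0.29, to 140.0 CPM in wild type and 75.1 CPM in knockout. Il22ra2 (ENSMUSG00000039760; chromosome 10, 19621998 to 19634681), which encodes the soluble antagonist of interleukin-22, rose by 4.28 ± 0.17. Mt4 rose by 4.25 ± 0.34 and Galnt15 by 4.05 ± 0.30, and Upk3b reached 2.35 CPM in wild type and 0.966 CPM in knockout. Mmp13 changed by -5.13 ± 0.39, reaching 0.255 CPM in wild type and 1.45 CPM in knockout, Jakmip2 changed by -4.66 ± 0.29, Mmp3 by -4.56 ± 0.27, Ddah1 by -4.52 ± 0.48 and the lipoxygenase Alox8 by -4.49 ± 1.19. Uox, which encodes urate oxidase, was at 30.1 CPM in wild type and 11.9 CPM in knockout under TPA, and at 0.191 and 0.785 CPM with FA.

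Glucocorticoid targets had 10 of 20 up (13 adjusted over the list alone) and none down, with a median of 0.88 (camera adjusted p = 3.13e-09, adjusted p = 0.212 with an estimated correlation). The glucocorticoid receptor co-chaperone Fkbp5 rose by 1.90 ± 0.20 and the transcription factor Zbtb16 by 2.40 ± 0.26. Epidermal differentiation had 23 of 38 up and none down (29 up and 2 down adjusted over the list alone), with a median of 0.68 (camera adjusted p = 5.49e-19, adjusted p = 0.212 with an estimated correlation), including the suprabasal keratin Krt10 (1.89 ± 0.15) and Lce1m (2.17 ± 0.11). Basal and hemidesmosome genes had 7 of 14 up and 2 down (3 down adjusted over the list alone; camera adjusted p = 0.00605, adjusted p = 0.229 with an estimated correlation), among them Krt15 (1.66 ± 0.23) and Dst (1.24 ± 0.13). Stress keratins had 11 of 17 down (13 adjusted over the list alone) and a median of -1.92 (camera adjusted p = 1.88e-11, adjusted p = 0.247 with an estimated correlation), with Krt17 at -2.16 ± 0.18 and Sprr2f at -3.67 ± 0.41. Proteases and EGFR ligands had 9 of 17 down and 1 up (13 down and 3 up adjusted over the list alone), with a median of -1.14 (camera adjusted p = 2.48e-08, adjusted p = 0.0958 with an estimated correlation), and Tnc changed by -3.64 ± 0.12. Cytokines and chemokines had 11 of 21 down and 1 up (12 down and 2 up adjusted over the list alone), with a median of -1.27 (camera adjusted p = 0.00019, adjusted p = 0.212 with an estimated correlation). Il19 was at 7.15 CPM in wild type and 3.01 CPM in knockout under TPA and at 0.127 and 0.181 CPM with FA. Antimicrobial genes had 4 of 12 down and 1 up (8 down adjusted over the list alone) and a median of -1.73 (camera adjusted p = 0.000311, adjusted p = 0.339 with an estimated correlation). Defb3 changed by -2.78 ± 0.61, while the acute phase gene Saa3 rose by 1.38 ± 0.28.

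NF-kB feedback genes had 9 of 18 down (11 adjusted over the list alone) and none up (camera adjusted p = 4.85e-06, adjusted p = 0.247 with an estimated correlation), with the receptor Cd40 at -1.80 ± 0.28 and Bcl3 at -1.35 ± 0.23. Interferon response genes had 6 of 22 down (8 down and 1 up adjusted over the list alone) and a median of -0.65 (camera adjusted p = 2.74e-06, adjusted p = 0.339 with an estimated correlation), with Oasl2 at -2.15 ± 0.37 and Stat2 at -0.87 ± 0.13. Glycolysis had 6 of 15 down (7 adjusted over the list alone; camera adjusted p = 1.15e-07, adjusted p = 0.298 with an estimated correlation), led by Hk2 (-1.22 ± 0.15). Hypoxia-associated genes had 4 of 14 down (9 down and 1 up adjusted over the list alone; camera adjusted p = 0.000259, adjusted p = 0.247 with an estimated correlation), with Bhlhe40 at -1.49 ± 0.14 and Vegfa at -1.12 ± 0.18. Oxidative phosphorylation had 4 of 26 down (10 adjusted over the list alone; camera adjusted p = 1.65e-07, adjusted p = 0.339 with an estimated correlation). Cell cycle genes had 2 of 36 down (0 adjusted over the list alone), Mcm5 (-0.38 ± 0.10) and Uhrf1 (-0.41 ± 0.11). The list median was -0.24 (camera adjusted p = 8.29e-06, adjusted p = 0.339 with an estimated correlation). Without the knockout FA+TPA library that median was -0.06 and the call was lost. AP-1 genes (camera adjusted p = 0.625), ATF4 targets (0.0866), cholesterol synthesis (0.707) and sebaceous genes (0.448) were not called. Without the knockout TPA library ATF4 targets (0.0281) and sebaceous genes (7.8e-06) were called lower, and without the wild-type TPA library cholesterol synthesis was called higher (0.0147). The cholesterol list had a median of -0.03 but a mean of 0.02 and a positive test direction.

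Neutrophil genes had 3 of 6 down (4 down and 1 up adjusted over the list alone; camera adjusted p = 0.00511, adjusted p = 0.298 with an estimated correlation), with Csf3r at -2.67 ± 0.34 and Cxcr2 at -1.44 ± 0.24. The neutrophil call was lost without the knockout TPA library (camera adjusted p = 0.148) and without the knockout FA+TPA library (0.0568). Macrophage genes were split, C1qa rising by 1.22 ± 0.18 and Mrc1 changing by -2.44 ± 0.45, and the list was not called (camera adjusted p = 0.992, with a median of -0.05, a mean of -0.38 and a positive test direction). Langerhans (camera adjusted p = 0.574) and T cell (0.574) lists were not called either. The Langerhans median was -0.26 and its mean 0.05. Skeletal muscle transcripts had a median of 1.94 with no member past the test over all genes (7 up adjusted over the list alone; camera adjusted p = 0.000259, adjusted p = 0.517 with an estimated correlation). That call was lost without the knockout TPA library (camera adjusted p = 0.148). The adipocyte list was higher, with 1 of 8 up (2 adjusted over the list alone; camera adjusted p = 0.0272, adjusted p = 0.49 with an estimated correlation), and the fibroblast list lower, with 1 of 11 down (camera adjusted p = 0.0447, adjusted p = 0.584 with an estimated correlation). The adipocyte call was lost without the knockout TPA library (0.111) or the knockout FA+TPA library (0.149), and the fibroblast call without the knockout TPA library or the wild-type FA+TPA library (0.151 each), without wild-type vehicle replicate 1 (0.0565), or with RLE normalisation (0.054). Txnip rose by 2.17 ± 0.36 and Sesn1 by 0.71 ± 0.14, while Sesn2 (-0.15 ± 0.13), Sesn3 (-0.04 ± 0.13), Tsc1 (-0.08 ± 0.10), Tsc2 (0.10 ± 0.09) and Ddit4l (0.38 ± 0.60) did not pass.

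Against TPA alone, 1929 genes passed the test, 1099 up and 830 down, of which 435 and 401 changed by more than 2-fold. The edgeR adjusted p of the genes named as changed with FA was at most 0.0423. The count was 571 without the wild-type FA+TPA library, 835 without the knockout FA+TPA library, 1002 without the wild-type TPA library and 987 without the knockout TPA library. The calls of Alox8 (edgeR adjusted p up to 0.235), Bcl3 (0.0909), Cxcr2 (0.0757), Defb3 (0.231), Mcm5 (0.21), Mrc1 (0.115), Oasl2 (0.128), Saa3 (0.23), Sesn1 (0.104), Uhrf1 (0.356) and Vegfa (0.054) ended without at least 1 of the 4 treated libraries. Those of Mcm5 and Uhrf1 also ended without either knockout vehicle library, with library size only (0.0864 and 0.0684) and with 1 mean per group (0.0993 and 0.0812), and that of Alox8 without wild-type vehicle replicate 2. With limma-voom the calls of Alox8 (adjusted p = 0.0982), Defb3 (0.187) and Saa3 (0.171) ended, and with DESeq2 that of Defb3 (0.185). In simulated data for this comparison over 19251 genes, 59% of 2-fold and 87% of 4-fold changes were recovered.

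Skin given FA before TPA was also compared with vehicle. Stress keratins, cell cycle genes, glycolysis and differentiation genes were above vehicle, and interferon response, Langerhans and T cell genes were below it. Sprr1b, a cornified envelope precursor, was higher by 6.87 ± 0.24, Krt6b by 6.61 ± 0.26, Sprr2g by 6.56 ± 0.32 and Sprr2h by 6.21 ± 0.20. The transcription factor gene Tcf23 was at most 0.227 CPM in vehicle and reached 17.2 CPM in wild type and 14.7 CPM in knockout, and Lce3d reached 13.2 and 16.1 CPM from at most 0.155 CPM. The interferon-induced helicase gene Ddx60 changed by -3.27 ± 0.40, Ifitm6 by -4.16 ± 0.33, Wfdc21 by -3.59 ± 0.17, the cation channel gene Trpm3 by -3.62 ± 0.40, Serpina3b by -3.27 ± 0.54 and the phosphodiesterase gene Pde1c by -3.10 ± 0.30.

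Of 17 stress keratin genes, 16 were up, with a median of 4.78 (camera adjusted p = 1.36e-14, adjusted p = 0.185 with an estimated correlation). Epidermal differentiation had 32 of 38 up (33 adjusted over the list alone) and 2 down, with a median of 1.08 (camera adjusted p = 9.25e-19, adjusted p = 0.185 with an estimated correlation), including Lce1h (2.40 ± 0.11) and Lce1e (1.81 ± 0.09). Antimicrobial genes had 9 of 12 up (camera adjusted p = 1.16e-06, adjusted p = 0.272 with an estimated correlation), and Saa3 went from at most 0.0454 CPM in vehicle to 4.39 CPM in wild type and 7.79 CPM in knockout. Cytokines had 9 of 21 up and 1 down (9 up and 3 down adjusted over the list alone; camera adjusted p = 0.000587, adjusted p = 0.185 with an estimated correlation), with the interleukin-36 gene Il1f8 at 2.26 ± 0.15. Proteases and EGFR ligands had 13 of 17 up and 1 down (camera adjusted p = 5.78e-06, adjusted p = 0.185 with an estimated correlation), with the EGFR ligand gene Hbegf at 2.42 ± 0.20 and Tnc at 1.39 ± 0.10. Cell cycle genes had 28 of 36 up (29 adjusted over the list alone; camera adjusted p = 4.95e-16, adjusted p = 0.185 with an estimated correlation), with Cdc20 at 2.24 ± 0.12. AP-1 genes had 9 of 14 up (11 adjusted over the list alone; camera adjusted p = 0.000343, adjusted p = 0.185 with an estimated correlation), with Fosl1 at 2.08 ± 0.17. All 15 glycolysis genes were up (camera adjusted p = 3.87e-12, adjusted p = 0.185 with an estimated correlation), with Ldha at 1.48 ± 0.10. ATF4 targets had 14 of 17 up (15 adjusted over the list alone; camera adjusted p = 5.41e-08, adjusted p = 0.185 with an estimated correlation), and hypoxia genes 7 of 14 up (camera adjusted p = 0.00591, adjusted p = 0.258 with an estimated correlation). Cholesterol synthesis had 12 of 23 up (12 up and 1 down adjusted over the list alone; camera adjusted p = 8.79e-05, adjusted p = 0.403 with an estimated correlation), and oxidative phosphorylation 8 of 26 up (camera adjusted p = 0.000862, adjusted p = 0.403 with an estimated correlation). Basal genes (camera adjusted p = 0.178), NF-kB feedback genes (0.87) and glucocorticoid targets (0.145) were not called. The NF-kB list had a median of -0.01, a mean of 0.11 and a positive test direction.

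Interferon response genes had 12 of 22 down and 2 up, with a median of -0.65 (camera adjusted p = 0.00155, adjusted p = 0.351 with an estimated correlation), a call lost without the knockout FA+TPA library (camera adjusted p = 0.106). Usp18 changed by -1.72 ± 0.20, and Ifit1 was at 0.0636 CPM in wild type and 0.181 CPM in knockout, against 0.565 and 0.983 CPM in wild-type vehicle and 5.11 and 2.86 CPM in knockout vehicle. Langerhans genes had 7 of 8 down (camera adjusted p = 5.78e-06, adjusted p = 0.185 with an estimated correlation), with Cd207 at -1.46 ± 0.13 and the invariant chain gene Cd74 at -1.11 ± 0.12. T cell genes had 7 of 13 down and 1 up (8 down adjusted over the list alone; camera adjusted p = 0.000689, adjusted p = 0.185 with an estimated correlation), with Cd3e at -2.15 ± 0.17. Neutrophil genes had 4 of 6 up (6 adjusted over the list alone; camera adjusted p = 0.00114, adjusted p = 0.217 with an estimated correlation), and macrophage genes 6 of 11 up (6 up and 1 down adjusted over the list alone; camera adjusted p = 0.000587, adjusted p = 0.317 with an estimated correlation), with C1qc at 4.15 ± 0.24. The adipocyte list had 4 of 8 up and 1 down (camera adjusted p = 0.0385, adjusted p = 0.38 with an estimated correlation). It was not called without the knockout FA+TPA library (0.18), wild-type vehicle replicate 1 (0.08) or knockout vehicle replicate 1 (0.0838). Skeletal muscle genes had a median of 1.24 with no member past the test (camera adjusted p = 0.0793), but were called higher with 1 mean per group (9.7e-05) and with library size only (0.00395). Their median was 1.84 without knockout vehicle replicate 1 and 2.53 without the knockout FA+TPA library. Sesn1 (-0.72 ± 0.12), Sesn3 (-0.54 ± 0.11), Tsc1 (-0.38 ± 0.09) and Txnip (-0.93 ± 0.30) were below vehicle.

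Against vehicle, 6076 genes passed the test with FA+TPA, 3347 up and 2729 down, of which 1170 and 819 changed by more than 2-fold, and the edgeR adjusted p of the genes named as changed was at most 0.0386. With scaling by library size only, all genes shifted by a median of -0.233 and the split was 1953 up and 4982 down. The count was 2652 without the wild-type FA+TPA library and 3159 without the knockout FA+TPA library. Without 1 of those libraries the calls of Sesn3 (edgeR adjusted p = 0.0662), Tsc1 (up to 0.11) and Txnip (up to 0.199) ended, and that of Txnip also without wild-type vehicle replicate 2 or knockout vehicle replicate 1, with limma-voom (0.0594) and with DESeq2 (0.0941). In simulated data for this comparison over 19251 genes, 81% of 2-fold and 88% of 4-fold changes were recovered.

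**Figure D3:**
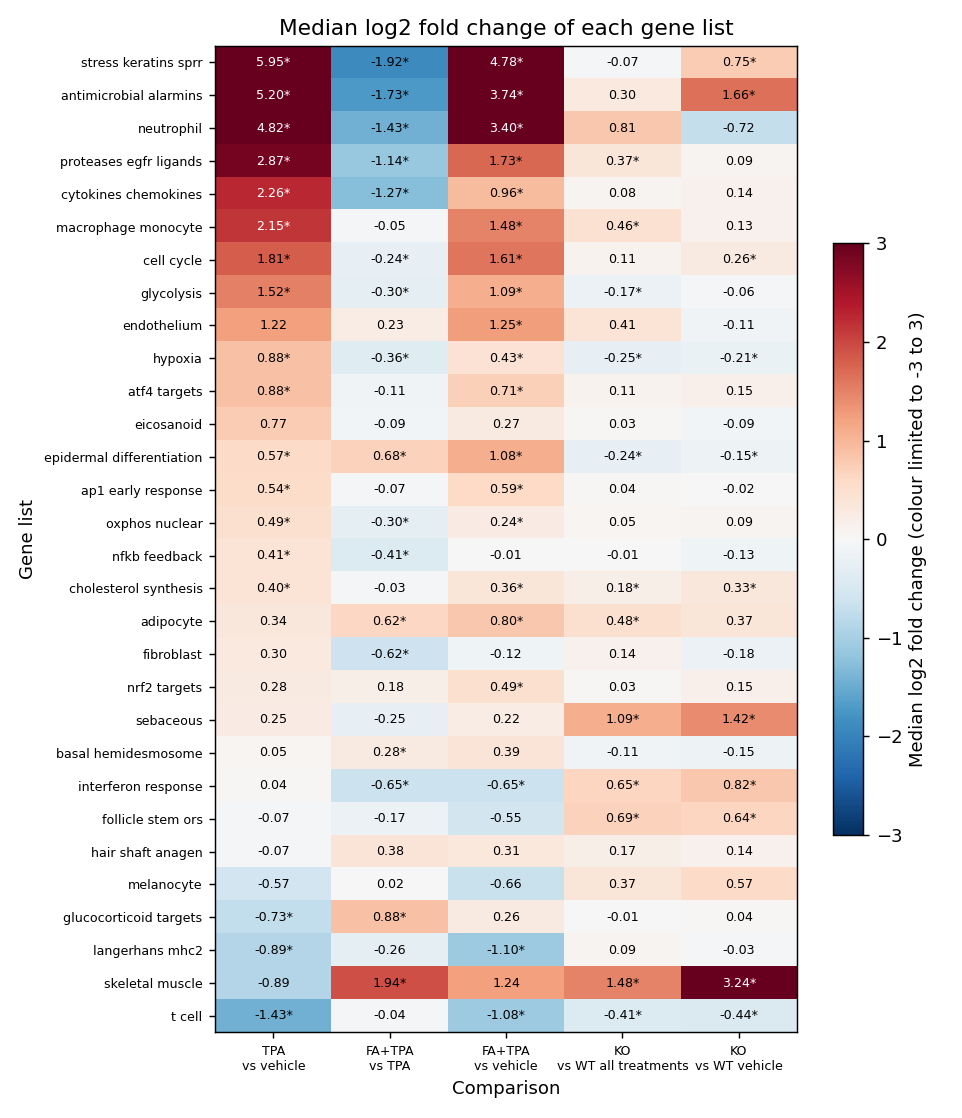
Median log2 fold change of each of 30 gene lists (vertical axis) in 5 comparisons (horizontal axis). The colour scale is limited to between -3 and 3, and an asterisk marks a camera adjusted p under 0.05 with the preset correlation. Stress keratins stood at 5.95 with TPA and -1.92 with FA before TPA, and glucocorticoid targets at -0.73 and 0.88.

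Knockout and wild type were compared over all 3 treatments, 4 libraries against 4 matched by treatment. The interferon response and sebaceous gland lists were called higher in knockout, and the epidermal differentiation list slightly lower. On the mixed background, differences in inherited alleles cannot be told apart from REDD1 loss in these samples. Oasl2 (ENSMUSG00000029561; chromosome 5, 114896936 to 114912234), an interferon-induced gene, was higher by 1.73 ± 0.25, Ifit1 by 2.22 ± 0.32 and the interferon-induced GTPase gene Gbp2b by 1.88 ± 0.15. The melanocortin receptor gene Mc5r, expressed in sebaceous glands, was higher by 1.54 ± 0.28, the small GTPase gene Rab6b by 2.35 ± 0.25, Cyp3a57 by 1.88 ± 0.24 and Aadacl4 by 1.76 ± 0.29. H60c, a ligand of the receptor NKG2D, differed by -2.29 ± 0.26. Several of the transcripts furthest below wild type, among named genes with a mean log2 CPM of at least 2, are uncertain, because reads from near-identical copies or from the opposite strand cannot be told apart in these counts. These were the antisense gene BC018473 (-6.31 ± 0.32), the Tpm3 copy Tpm3-rs7 (-3.83 ± 0.18), Rps3a1 (-2.72 ± 0.17) and the pseudogene Ywhaq-ps1 (-2.69 ± 0.23).

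Interferon response genes had 9 of 22 higher (15 adjusted over the list alone) and none lower, with a median of 0.65 (camera adjusted p = 2.93e-13, adjusted p = 0.371 with an estimated correlation). Under TPA 21 of the 22 and under FA+TPA 17 of the 22 members were higher in knockout than in wild type. Sebaceous genes had 7 of 10 higher (10 adjusted over the list alone), with a median of 1.09 (camera adjusted p = 5.34e-12, adjusted p = 0.371 with an estimated correlation), including the wax synthase gene Awat2 (0.88 ± 0.17). Their median difference between knockout and wild type was 1.28 and 1.71 in the knockout vehicle replicates and 1.24 under FA+TPA, but 0.24 under TPA, below the 0.66 between the wild-type vehicle replicates. Follicle stem cell and outer root sheath genes had 3 of 9 higher (6 higher and 1 lower adjusted over the list alone; camera adjusted p = 0.000337, adjusted p = 0.371 with an estimated correlation), including the transcription factor genes Sox9 (0.69 ± 0.12) and Lhx2 (0.98 ± 0.20). Epidermal differentiation had 12 of 38 lower (15 adjusted over the list alone) and none higher, with a median of -0.24 (camera adjusted p = 9.24e-16, adjusted p = 0.371 with an estimated correlation), among them Lce1j (-1.08 ± 0.12) and Lce1d (-0.43 ± 0.06), whose similar sequences the counting could split. Hypoxia genes had 3 of 14 lower (6 adjusted over the list alone; camera adjusted p = 3.53e-05, adjusted p = 0.371 with an estimated correlation), with Egln3 at -0.39 ± 0.08 and Bhlhe40 at -0.46 ± 0.10. Glycolysis had 2 of 15 lower (5 adjusted over the list alone; camera adjusted p = 5.78e-05, adjusted p = 0.5 with an estimated correlation), Eno1 (-0.78 ± 0.11) and Pfkl (-0.38 ± 0.08).

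Skeletal muscle genes were higher as a list with no member past the test over all genes (8 adjusted over the list alone) and a median of 1.48 (camera adjusted p = 1.66e-05, adjusted p = 0.5 with an estimated correlation). Their median difference was 3.93 and 2.38 in the knockout vehicle replicates, but 0.37 under TPA and 0.10 under FA+TPA, below the 1.20 between the wild-type vehicle replicates. Macrophage genes had 1 of 11 higher, Ccr2 (1.58 ± 0.36; camera adjusted p = 0.000321 for the list, adjusted p = 0.5 with an estimated correlation), a call lost without the TPA library of either genotype (camera adjusted p = 0.166). Cholesterol synthesis had 1 of 23 higher (camera adjusted p = 0.00668, adjusted p = 0.696 with an estimated correlation), a call lost without wild-type vehicle replicate 1 (0.261) or knockout vehicle replicate 2 (0.0741). T cell genes had 3 of 13 lower and 2 higher (5 lower and 3 higher adjusted over the list alone; camera adjusted p = 0.0228, adjusted p = 0.5 with an estimated correlation), with Cd3e at -0.62 ± 0.12 and Cd247 at -0.76 ± 0.15. That call was lost without either wild-type vehicle library (0.0825 and 0.0597) or knockout vehicle replicate 2 (0.0991), and with 1 mean per group (0.241). The protease list had 1 of 17 higher, Tnc (0.60 ± 0.08; 2 higher and 1 lower adjusted over the list alone; camera adjusted p = 0.0446 for the list, adjusted p = 0.478 with an estimated correlation), and lost its call without any of 6 libraries (between 0.0539 and 0.156). The adipocyte list was higher with no member past the test over all genes (2 adjusted over the list alone; camera adjusted p = 0.0221, adjusted p = 0.5 with an estimated correlation) and was not called without wild-type vehicle replicate 1 (0.0767) or either FA+TPA library (0.0992 and 0.0991).

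Lists for cytokines (camera adjusted p = 0.206), antimicrobial genes (0.876), stress keratins (0.206), basal genes (0.0889), cell cycle (0.181), NF-kB feedback (0.925), AP-1 (0.316), glucocorticoid targets (0.992), ATF4 targets (0.181), oxidative phosphorylation (0.206), neutrophils (0.0941), Langerhans cells (0.541), fibroblasts (0.316), endothelium (0.181) and melanocytes (0.0941) were not called. Several were called with 1 library left out. Without the TPA library of either genotype, antimicrobial genes (camera adjusted p up to 0.00158), stress keratins (0.000454) and oxidative phosphorylation (0.00286) were higher. Stress keratins were instead lower without either FA+TPA library (up to 0.00514), wild-type vehicle replicate 1 (0.0444) or knockout vehicle replicate 2 (0.0421). Cell cycle (up to 0.00151) and melanocyte genes (0.0265) were higher without either FA+TPA library, cell cycle also with library size only (0.0449). Neutrophil (0.039), fibroblast (0.0217) and endothelial genes (0.022) were higher without knockout vehicle replicate 1, neutrophil genes also without wild-type vehicle replicate 1 (0.0491) and fibroblast genes without wild-type vehicle replicate 2 (0.0387). The antimicrobial list had a median of 0.30 and a mean of 0.06 with a negative test direction, stress keratins a median of -0.07 and a mean of 0.08, and NF-kB a median of -0.01 with a positive direction. Over all treatments 690 genes differed, 382 higher and 308 lower in knockout, and 159 and 137 by more than 2-fold. The edgeR adjusted p of the genes named as different was at most 0.047. Of the genes related to REDD1, Sesn3 was higher by 0.37 ± 0.09, while Sesn1 (0.04 ± 0.10), Sesn2 (-0.02 ± 0.09), Tsc1 (0.11 ± 0.07), Tsc2 (-0.16 ± 0.07), Txnip (0.11 ± 0.24) and Ddit4l (0.67 ± 0.42) did not pass. With scaling by library size only the split was 640 higher and 233 lower. The count was 382 and 360 without knockout vehicle replicate 1 or 2, 299 without the wild-type FA+TPA library and 288 without the knockout FA+TPA library. The calls of Sesn3, Pfkl, Cd247, Ccr2, Egln3, Lhx2, Awat2, Bhlhe40, Cd3e and Mc5r ended without at least 1 library (edgeR adjusted p up to 0.23). Leaving out either TPA library, or either FA+TPA library, is nearly the same genotype test. With 1 mean per group the calls of Ifit1 (0.186), Sesn3, Pfkl, Cd247, Lhx2, Bhlhe40 and Cd3e ended, with library size only those of Pfkl, Egln3 and Bhlhe40 (edgeR adjusted p up to 0.0688), and with RLE normalisation that of Sesn3 (0.051). In simulated data for this comparison over 19251 genes, 78% of 2-fold and 96% of 4-fold changes were recovered.

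In vehicle-treated skin, 2 knockout libraries were compared with 2 wild-type libraries. Among the lists, skeletal muscle transcripts differed most: 10 of 14 were higher in knockout (14 adjusted over the list alone), with a median of 3.24 (camera adjusted p = 4.2e-18, adjusted p = 0.63 with an estimated correlation). The myosin heavy chain gene Myh1 was higher by 4.04 ± 0.40, at 25.3 and 22.6 CPM in knockout against 2.43 and 0.517 CPM in wild type. Mybpc2 (4.45 ± 0.70), Tnnt3 (4.01 ± 0.61), Ckm (3.60 ± 0.58) and Tnni2 (3.33 ± 0.46), which also encode muscle proteins, and the imprinted noncoding RNA H19 (3.85 ± 0.58) were higher too. Sebaceous genes had 9 of 10 higher (10 adjusted over the list alone), with a median of 1.42 (camera adjusted p = 1.39e-17, adjusted p = 0.63 with an estimated correlation), led by Dgat2l6 (2.35 ± 0.32) and Mc5r (1.95 ± 0.27). Interferon response genes had 4 of 22 higher (15 adjusted over the list alone), with a median of 0.82 (camera adjusted p = 2.49e-13, adjusted p = 0.63 with an estimated correlation), including Oasl2 (2.14 ± 0.30) and Ifit1 (2.34 ± 0.42).

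Stress keratin and small proline-rich genes had 2 of 17 higher (8 adjusted over the list alone), the stefin genes Stfa3 (2.85 ± 0.30) and Stfa1 (0.938 and 2.04 CPM against 0.170 and 0.207 CPM in wild type), whose family members share sequence (camera adjusted p = 4.6e-05, adjusted p = 0.63 with an estimated correlation). The list median was 0.75, against 0.31 without knockout vehicle replicate 2 and 1.28 without wild-type vehicle replicate 2. Antimicrobial genes had a median of 1.66 with no member past the test over all genes (6 adjusted over the list alone; camera adjusted p = 0.00184, adjusted p = 0.66 with an estimated correlation). That call was lost without knockout vehicle replicate 2 (camera adjusted p = 0.156), at a median of 0.31. Cell cycle genes had 3 of 36 higher (10 adjusted over the list alone; camera adjusted p = 4.1e-06, adjusted p = 0.63 with an estimated correlation), including the mitotic kinesin genes Cenpe (0.79 ± 0.15) and Kif11 (0.62 ± 0.13). Cholesterol synthesis had 1 of 23 higher (2 adjusted over the list alone; camera adjusted p = 8.15e-05, adjusted p = 0.66 with an estimated correlation), and follicle genes 1 of 9 higher (2 higher and 1 lower adjusted over the list alone), Sox9 (0.84 ± 0.17; camera adjusted p = 0.00488 for the list, adjusted p = 0.63 with an estimated correlation). Both calls were lost without wild-type vehicle replicate 1 (0.331 and 0.266). Hypoxia genes were lower with 1 of 14 past the test, Bhlhe40 (-0.71 ± 0.12; camera adjusted p = 0.00607 for the list, adjusted p = 0.63 with an estimated correlation), a call lost without wild-type vehicle replicate 1 (0.278) or knockout vehicle replicate 1 (0.0833). The epidermal differentiation list was lower at a median of -0.15 (camera adjusted p = 0.000394, adjusted p = 0.63 with an estimated correlation), with 2 of 38 higher and 1 lower (2 and 2 adjusted over the list alone). Its call was lost without wild-type vehicle replicate 2 (0.147) or knockout vehicle replicate 1 (0.107). Lce1j differed by -1.38 ± 0.13 and repetin, Rptn, by 2.70 ± 0.48. T cell genes were lower at a median of -0.44 (camera adjusted p = 0.00806, adjusted p = 0.653 with an estimated correlation), although the 1 of 13 past the test over all genes, Cd8a, was higher (2.55 ± 0.43; 2 higher and 6 lower adjusted over the list alone). That call was lost without knockout vehicle replicate 2 (0.46).

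In vehicle skin the lists for cytokines (camera adjusted p = 0.512), basal genes (0.0746), NF-kB feedback (0.171), AP-1 (0.512), proteases (0.163), glucocorticoid targets (0.811), glycolysis (0.39), ATF4 targets (0.0746), oxidative phosphorylation (0.0698), neutrophils (0.0746), macrophages (0.618), Langerhans cells (0.411), fibroblasts (0.877), adipocytes (0.171), NRF2 targets (0.0746) and melanocytes (0.0545) were not called. Without wild-type vehicle replicate 2, proteases (camera adjusted p = 0.0311), NRF2 targets (0.0308), oxidative phosphorylation (0.00698) and adipocytes (0.0311) were higher and basal genes lower (0.0221). Fibroblast genes were lower without wild-type vehicle replicate 1 (0.0317) or knockout vehicle replicate 2 (0.011), and melanocyte genes higher without the latter (0.0134). AP-1 genes were higher without knockout vehicle replicate 1 (0.0141) or 2 (0.0465), and adipocytes without replicate 1 (8.09e-05). The AP-1 list had a median of -0.02 and a mean of 0.22. Besides Ddit4 (-2.71 ± 0.13), the named genes furthest below wild type among those with a mean log2 CPM of at least 2 were BC018473 (-6.64 ± 0.43), Tpm3-rs7 (-3.85 ± 0.30), Rps3a1 (-3.12 ± 0.20), Rpl29 (-2.54 ± 0.23) and Rpl34 (-2.20 ± 0.17), with the same uncertainty about shared reads. The sestrins, Tsc1, Tsc2, Txnip and Ddit4l did not pass in vehicle skin, the nearest being Sesn3 at 0.37 ± 0.15 (edgeR adjusted p = 0.349). In total 418 genes differed, 278 higher and 140 lower in knockout, 201 and 107 by more than 2-fold, and the edgeR adjusted p of the genes named as different was at most 0.0382. The count was 960 without wild-type vehicle replicate 1 and 1465 without wild-type vehicle replicate 2. The calls of Bhlhe40 (edgeR adjusted p up to 0.0873) and Kif11 (0.183) ended without either knockout vehicle library, and those of Cenpe (0.0791) and Sox9 (0.243) without knockout vehicle replicate 2. With limma-voom the calls of Cenpe, Ckm, H19, Kif11, Mybpc2, Rptn, Sox9, Stfa1 and Tnnt3 ended (adjusted p up to 0.084), and with DESeq2 those of Ifit1 (0.0943) and Kif11 (0.0945). At a minimum count of 50 the calls of Kif11, Rptn and Sox9 ended (edgeR adjusted p up to 0.0652). In simulated data for this comparison over 19251 genes, 55% of 2-fold and 92% of 4-fold changes were recovered.

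**Figure D4:**
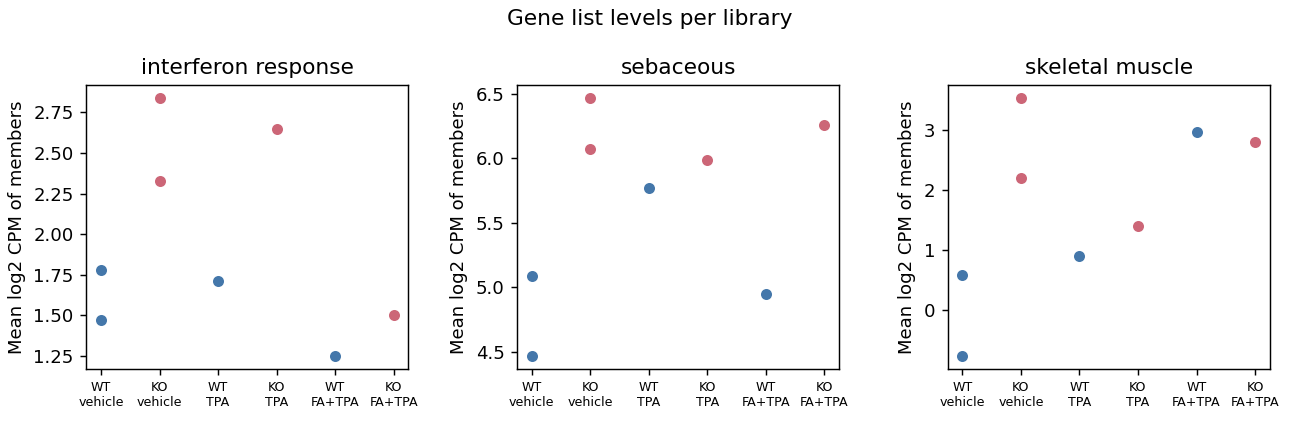
Mean log2 CPM (vertical axes, each with its own range) of the measured members of 3 gene lists in each library (blue, wild type; red, REDD1 knockout). The skeletal muscle list stood at 3.53 and 2.20 in knockout vehicle, at 0.57 and -0.77 in wild-type vehicle, and at 2.96 and 2.79 under FA+TPA in wild type and knockout.

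Whether REDD1 altered the response to TPA or to FA was tested with the interaction of genotype and treatment. The TPA responses of the genotypes ran largely parallel: of 1965 genes that changed by more than 2-fold in wild type, among 12001 with a mean log2 CPM of at least 2, 1936 (98.5%) went the same way in knockout. Across these genes, which are not independent replicates, Pearson's r was 0.916 and Spearman's rho 0.884, and the median ratio of the knockout to the wild-type change was 0.85. For FA+TPA against TPA, 616 of 658 genes (93.6%) went the same way, with r of 0.745, rho of 0.63 and a median ratio of 0.73. Choosing genes by their wild-type change favours a ratio below 1. Genes that rose by more than 2-fold with FA in wild type had a median rise of 1.34 there and 1.13 in knockout, whereas those chosen in knockout had 1.31 in knockout and 1.21 in wild type. With TPA the medians were 1.54 in wild type and 1.33 in knockout for genes chosen in wild type, and 1.48 in knockout and 1.59 in wild type for those chosen in knockout. The wild-type and knockout responses share no library.

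A single gene passed the test for a different TPA response, Lgals4 (ENSMUSG00000053964; chromosome 7, 28833854 to 28841708), which encodes the lectin galectin-4. It was at 10.8 and 10.1 CPM in wild-type vehicle and 11.2 and 9.81 CPM in knockout vehicle, and at 46.6 CPM in wild type against 7.86 CPM in knockout under TPA (-2.57 ± 0.26, edgeR adjusted p = 0.0326). The call ended with a minimum count of 50 (adjusted p = 0.105) and with limma-voom (0.0806). Under FA+TPA it was at 79.5 and 11.3 CPM. The interaction for Ddit4 itself was -1.14 ± 0.23 and did not pass (edgeR adjusted p = 0.32), but passed without either wild-type vehicle library (0.000107 and 0.00225). For the TPA response edgeR called 1 gene, with 1014 at an unadjusted p under 0.05, DESeq2 called 11 and limma-voom 0. For the FA response edgeR called 0 genes, with 613 at an unadjusted p under 0.05, DESeq2 called 7 and limma-voom 0.

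As lists, stress keratins rose less with TPA in knockout by a median of -1.31 (camera adjusted p = 7.77e-16, adjusted p = 0.597 with an estimated correlation), with no member past the test over all genes (11 lower adjusted over the list alone). Antimicrobial genes differed by -2.31 (4 lower adjusted over the list alone; camera adjusted p = 1.79e-10, adjusted p = 0.597 with an estimated correlation). The antimicrobial median difference between knockout and wild type was 0.27 and 1.53 in the knockout vehicle replicates and -0.72 under TPA. Much of the interaction thus came from knockout vehicle replicate 2. The alarmin gene S100a8, for example, was at 0.452 and 0.466 CPM in wild-type vehicle and 1.22 and 3.90 CPM in knockout vehicle. Under TPA it was at 367 CPM in wild type and 134 CPM in knockout. Neutrophil genes differed by 1.60 (2 higher adjusted over the list alone; camera adjusted p = 0.000112, adjusted p = 0.597 with an estimated correlation) and macrophage genes by 0.70 (2 higher adjusted over the list alone; camera adjusted p = 7.33e-05, adjusted p = 0.597 with an estimated correlation). Csf3r reached 11.9 CPM in wild type and 34.8 CPM in knockout under TPA, and Mmp12, which encodes macrophage elastase, 2.96 and 19.3 CPM. Skeletal muscle genes differed by -2.54 (3 lower adjusted over the list alone; camera adjusted p = 1.02e-12, adjusted p = 0.597 with an estimated correlation), and sebaceous genes by -1.29 (8 lower adjusted over the list alone; camera adjusted p = 8.74e-13, adjusted p = 0.597 with an estimated correlation). For the FA response, stress keratins differed by 1.03 (8 higher adjusted over the list alone; camera adjusted p = 2.58e-17, adjusted p = 0.695 with an estimated correlation), antimicrobial genes by 0.77 (4 higher adjusted over the list alone; camera adjusted p = 7.33e-09, adjusted p = 0.695 with an estimated correlation), sebaceous genes by 1.03 (2 higher adjusted over the list alone; camera adjusted p = 5.86e-10, adjusted p = 0.695 with an estimated correlation) and macrophage genes by -0.79 (camera adjusted p = 0.000113, adjusted p = 0.695 with an estimated correlation). Glucocorticoid targets were not called for the FA response, with a median of -0.15 (camera adjusted p = 0.185). Of the lists not called, 9 were called for the TPA response without at least 1 vehicle library. For the FA response, cytokines (camera adjusted p = 0.0761) and skeletal muscle (0.053) were called without any 1 of the vehicle libraries. AP-1 genes (0.0758) were called without either wild-type vehicle library. Cytokines were also called with library size only (0.0195) and muscle with RLE normalisation (0.0387). Both interactions rest on the same 2 TPA libraries, which enter them with opposite sign, and on single treated libraries assumed to vary like the vehicle pairs. The TPA interaction count was 6 without either FA+TPA library. With 1 vehicle library left out, the spread came from the other genotype's pair alone, so gene and list calls rest on that pair. In simulated data over 19251 genes, 15% of 2-fold and 59% of 4-fold changes were recovered for the TPA interaction, and 6% and 55% for the FA interaction.

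**Figure D5:**
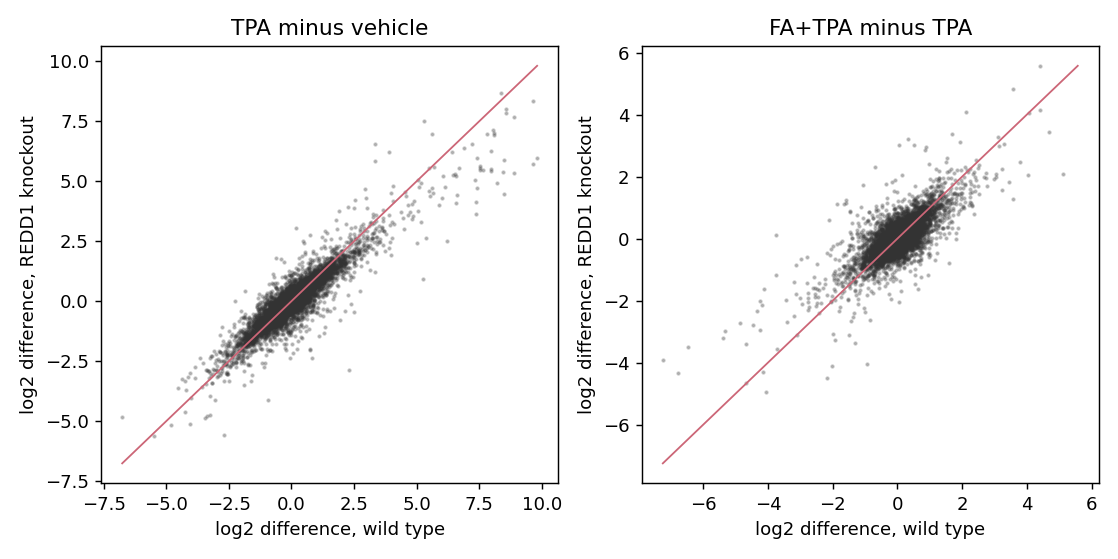
Log2 change of 12001 genes with TPA (left) and with FA before TPA relative to TPA alone (right), in wild type (horizontal axis) and REDD1 knockout (vertical axis). Each point is a gene and the line marks equal change, with r of 0.916 on the left and 0.745 on the right.

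How far FA lowered TPA-raised genes was also described across genotypes, choosing genes in the libraries of one genotype and measuring them in the other. The 200 genes that rose most with TPA in wild type were lower with FA in knockout by a median of -0.72, 179 of them (89.5%) going down. The 200 chosen in knockout were lower with FA in wild type by a median of -1.06, 177 of them (88.5%) going down. Among 10000 random lists matched on expression, the lowest medians were -0.09 and -0.11. These are single libraries, so the values describe these libraries and have no replicate check.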

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

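The tests of explanations for the muscle and TPA-raised transcripts were chosen after the results were seen, while the interaction tests were planned.

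Results stood out here because the genotypes differed in their response by the interaction test. For single genes this was Lgals4 in the TPA response (-2.57). For lists in the TPA response, the medians of the knockout minus the wild-type change were -2.31 for antimicrobial genes, -1.31 for stress keratins, -0.22 for epidermal differentiation, -0.29 for cell cycle, -0.27 for glycolysis, -0.35 for cholesterol synthesis, -0.39 for NRF2 targets, -0.24 for oxidative phosphorylation, 1.60 for neutrophils, 0.70 for macrophages, -2.54 for skeletal muscle and -1.29 for sebaceous genes. With an estimated correlation the adjusted p was 0.597 for each of these lists except cholesterol synthesis (adjusted p = 0.675 with an estimated correlation). The glycolysis call ended without knockout vehicle replicate 2 (camera adjusted p = 0.0576), and the NRF2 call also without wild-type vehicle replicate 1 (0.389) or with library size only (0.0518).

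In the FA response the medians were 0.77 for antimicrobial genes, 1.03 for stress keratins, 0.07 for epidermal differentiation, -0.22 for cell cycle, 0.23 for NF-kB feedback, 0.27 for cholesterol synthesis, -0.36 for interferon response, 0.27 for oxidative phosphorylation, -0.96 for neutrophils, -0.79 for macrophages and 1.03 for sebaceous genes. With an estimated correlation the adjusted p was 0.695, or 0.808 for epidermal differentiation, cholesterol synthesis and interferon response. With library size only, the epidermal differentiation median was -0.13 and its call ended (camera adjusted p = 0.264), as did the neutrophil call (0.104).

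Skeletal muscle transcripts were higher in knockout vehicle than in wild-type vehicle, by 3.93 and 2.38 in the knockout replicates, and this entered the muscle interaction. Deeper scraping with all dermal cell types alike was argued against, since the fibroblast median was -0.18, with 0.58 at most between vehicle replicates, and the endothelium median -0.11 (0.82). The adipocyte median was 0.37, with up to 1.26 between replicates. It was 1.11 without wild-type vehicle replicate 2 and 0.80 without knockout vehicle replicate 1, so adipocytes do not speak against deeper scraping. Muscle below the skin carried over in some scrapings stays possible. Wild-type skin under FA+TPA also held these transcripts, at a list mean of 2.96, and Myh1 there reached 40.6 CPM. That mean was 1.57 above the lowest knockout library, the TPA one. Knockout skin under FA+TPA was at 2.79, so an effect of FA would look the same, and this level does not single out carry-over. A genotype effect, in vehicle skin or under every treatment, stays open: the knockout minus wild-type medians of 0.10 under FA+TPA and 0.37 under TPA each compare single libraries, and vehicle replicates differed by up to 1.45.

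Stress keratin and antimicrobial lists, raised by TPA, were called higher in knockout vehicle. The antimicrobial median difference was 0.27 in knockout replicate 1, near the 0.25 between wild-type replicates, and 1.53 in replicate 2. The interaction holds both these vehicle differences and a lower TPA level in knockout. Knockout minus wild-type medians under TPA were -0.66 for stress keratins and -0.72 for antimicrobial genes. RNA of a TPA library mixed into knockout vehicle would have 1 share for all genes, so the lowest limit holds. Krt6b set it, at 0.343% of knockout or 0.233% of wild-type TPA RNA. Either left a median excess of 0.36 over the 29 list members (2 SE, 0.33, with 0.1 CPM added). This argues narrowly against mixing as the whole explanation. The test had also asked for an excess at the looser limits, and the 0.87% that Krt6a allowed left 0.12 (2 SE, 0.35). Mixing thus stays open as part of it. Earlier tests on how far the shares varied between genes had no reference for noise and decided nothing. That 1 knockout vehicle library alone carried the difference is open too: the stress keratin median was 0.31 in replicate 1, below the 0.44 between wild-type replicates, and 0.89 in replicate 2, yet without replicate 2 the stress keratin call was kept (camera adjusted p = 0.0107) and the antimicrobial call lost (0.156). A genotype effect on unstimulated epidermis stays open as well.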

How the results depend on the processing

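The removal of Gm26917 and Gm23935 was chosen after the results were seen, and the other alternatives were planned. No gene called in both changed sign between the reported setting and an alternative, and no named gene reversed. Under other settings, values of named genes kept their side of the threshold in 3233 cases, newly passed in 67 and ceased to pass in 68, and with 1 library left out in 2760, 144 and 182. Without Gm26917 and Gm23935 the counts of genes were 8842, 1909, 6094, 676, 437, 1 and 0 for TPA, FA+TPA against TPA, FA+TPA against vehicle, knockout over all treatments, knockout in vehicle and the TPA and FA interactions.

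Besides the fits with 1 library left out or with a replicate block, gene counts that moved by more than 1.5 times were these. Knockout over all treatments gave 1552 genes without a low-count filter, which tested 34515 genes, and 450 with 1 mean per group. Knockout in vehicle gave 219 genes at a minimum count of 50, which tested fewer genes, and 272 with DESeq2. The TPA interaction gave 3 genes with library size only, 21 without a filter, 0 at a minimum count of 50, 0 with limma-voom and 11 with DESeq2, and the FA interaction gave 7 with DESeq2. Where the construction does not show it, the cause was not tested. With an estimated correlation 0 lists were called in each of the 7 comparisons.

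With 1 library left out, counts ranged from 6049 to 8810 for TPA, 571 to 2367 for FA+TPA against TPA, 2652 to 6051 for FA+TPA against vehicle, 288 to 630 for knockout over all treatments, 440 to 1465 for knockout in vehicle, 6 to 365 for the TPA interaction and 51 to 183 for the FA interaction. These fits had fewer residual degrees of freedom, and a lone library was assumed to vary like the other groups. The interactions could not be estimated without a library of their own treated groups.

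Deviations of same-numbered vehicle libraries correlated at -0.059 over the tested genes, so replicate numbers did not pair the samples as a whole. Pairing in part of the genes stays open. From replicate 1 to 2 the skeletal muscle mean went from 0.57 to -0.77 in wild type and from 3.53 to 2.20 in knockout. The interferon response mean went opposite ways, from 1.47 to 1.78 in wild type and from 2.84 to 2.33 in knockout. A fit of the vehicle libraries with the replicate number as a block called 847 genes, more than 1.5 times the 418 reported, and without the block 473. The fall of TPA-raised genes with FA, for genes chosen in wild type, was -1.08 over 100 genes, -0.53 over 400, -1.07 with a mean log2 CPM of at least 0 and -0.81 with library size only. For genes chosen in knockout it was -1.55, -0.72, -1.38 and -0.95. Depth left transcripts near 3 counts, 0.133 to 0.178 CPM, unresolved.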

Other observations

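The tests of the transcripts lower in knockout under all treatments were chosen after the results were seen, as was the limit to splits balanced for treatment, while the test of other splits of the samples was planned.

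Further lists described lipid mediators, redox and appendages. Eicosanoid genes went both ways with TPA (8 of 14 up and 5 down, camera adjusted p = 0.393), the prostaglandin synthase Ptges rising by 1.30 ± 0.09 and the lipoxygenase Alox12 changing by -2.48 ± 0.16. FA before TPA moved both back, with Ptges at -0.68 ± 0.10 and Alox12 at 1.35 ± 0.18 against TPA alone (edgeR adjusted p at most 0.00256), though the call of Ptges ended without the wild-type FA+TPA library (0.058). NRF2 targets had 7 of 15 up and 3 down with TPA (4 down adjusted over the list alone; camera adjusted p = 0.197), yet the glutathione transferase Gsta4 rose by 5.81 ± 0.22, and FA changed it by -1.68 ± 0.21. Against vehicle under FA+TPA, 8 of 15 NRF2 targets were up and 1 down (camera adjusted p = 0.00406, adjusted p = 0.245 with an estimated correlation). Endothelial genes had 5 of 8 up and 1 down there (6 up adjusted over the list alone; camera adjusted p = 0.0257, adjusted p = 0.185 with an estimated correlation), a call that ended without the knockout FA+TPA library (0.098), and they were not called with TPA (0.0599), except higher with library size only (0.0126), with 1 mean per group (0.0491), without the wild-type TPA library (0.0241) or without knockout vehicle replicate 2 (0.0494).

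Follicle stem cell and outer root sheath genes were not called with TPA (camera adjusted p = 0.88), with 2 of 9 up and 3 down, but the companion layer keratin Krt75 rose by 3.3 ± 0.19 and changed by -2.54 ± 0.24 with FA, and the stem cell receptor Lgr6 changed by -2.47 ± 0.12 with TPA. Hair shaft (camera adjusted p = 0.78), sebaceous (0.726, but 0.019 without the knockout TPA library) and interferon response genes (0.746) were not called with TPA, the last with 4 of 22 up and 4 down, Mx1 at 1.89 ± 0.20 and Usp18 at -1.19 ± 0.19. Of the erythroid list 2 of 5 genes were measured, and 1 was lower with TPA (2 adjusted over the list alone), Hba-a1. It was between 0.454 and 1.45 CPM in vehicle and at 0.0616 and 0.0449 CPM under TPA, under the floor of 3 counts (edgeR adjusted p = 0.00168), and of the mitochondrially encoded list 0 of 13 were measured.

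The 690 genes that differed by genotype over all treatments were set against other splits of the 8 libraries into 4 and 4. Splits that put unequal numbers of a treatment's libraries on either side are not exchangeable with the real one. Of the 12 balanced splits, 1, the real one, gave as many genes and the highest other gave 0, but 12 splits are too few for a share under 0.05. Over all 34 splits that could be estimated the highest other gave 1. Every split but the real one mixed the genotypes on both sides, so genotype differences entered its spread, which can lower its count. These counts are therefore no reference for data without a genotype effect. Genes within 10 Mb of Ddit4 were not called more often than others: 4 of 126 (3.17%) against 3.58% elsewhere (Fisher's exact test, two-sided, p = 1).

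Besides Ddit4, 59 transcripts on 18 chromosomes were at least 4-fold lower in knockout under all 3 treatments, against 3 that were as much higher. A segment inherited with the targeted gene was argued against, since 0 of the 59 lay within 10 Mb of it, which allows up to 6.1%. Reads shared between gene copies that differ between the background strains may explain part of the set. Of the 59, 34 (57.6%) were pseudogenes or ribosomal protein genes, against 8.8% of 10830 other tested genes (Fisher's exact test, two-sided, p = 6.84e-21). Those genes lay within the set's range of mean expression but were not matched on it. An effect of REDD1 loss or of other background alleles on the remaining transcripts stays open, and no sequence was examined here.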
